A study of Bombyx mori with 12 samples.

How the data were processed

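Total RNA of ovaries dissected from female Bombyx mori pupae was sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The table holds 12 sample columns, 3 each for WT and TBH at P2 and P4, and 4 columns of group means, which equalled the mean of their samples within rounding. The deposited values are a normalized expression signal per transcript with 2 decimals whose unit is not named in the file or the labels. TPM over all listed genes would sum to the same total in every sample, but the sums ran from 468558.9 to 664133.6. This argues against TPM over the listed genes. TPM over a larger set cut to these genes is not excluded. Cufflinks and DESeq2 are named in the submitters' processing notes, without versions or their roles, and the aligner, the counting, the genome build and the annotation are not given in the sources used here. Samples were grouped by line and stage as in their titles. The treatment protocol of the labels states 5 female pupae and n = 3; whether a sample pools several pupae is not given in the sources used here.

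The table lists 15745 genes, of which 14623 have a gene model ID and 1122 a non-coding RNA ID, 2221 have a product description and 1785 a gene name. Names and products were taken from the table itself, since 0 IDs matched the reference name table. At 0 in all samples were 4536 genes, among them RPS24, RPS12 and RPL27, 3 of the 51 ribosomal protein genes of the list. At 0 in at least 1 sample and above 20 in another were 432 genes. An exact 0 may therefore be a failed estimate, so such values are given as listed at 0, values are given per sample for groups with a 0, and no fold is given against a group at 0. The listed values summed to 468558.9 to 664133.6 per sample. Read counts are not given in the sources used here, so the depth is unknown.

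The design, the gene lists, the rule for named genes and the other settings to be tried were fixed before the data were examined. The design foresaw edgeR for counts and limma for normalized values, and since the values are normalized, limma was used (edgeR was not run). Values were taken as log2(value + 1), without further scaling, for the 5235 genes with a value of at least 1 in at least 3 samples. Of these, 1827 were at 0 in at least 1 sample. The pseudocount of 1 makes changes of low values look smaller. A linear model with 1 mean per group was fitted to all 12 samples with limma (lmFit, contrasts.fit and eBayes with trend), and p-values were adjusted over all tested genes in each comparison after Benjamini and Hochberg, with a threshold of 0.05. The comparisons were TBH against WT at P2 and at P4, P4 against P2 in WT and in TBH, and the difference of the TBH effect between the stages. Errors of log2 changes are standard errors of the model, and errors of values are SDs of 3 samples. The fold given for a gene is the ratio of the group means. Shares of libraries were compared with two-sided exact permutation tests, where 3 samples against 3 give no p below 0.1.

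Of 32 gene lists, 30 had members in the table (amino acid and peptide transport and transposable element-like genes had none), 17 with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, adjusted over the 17 lists, and 13 were described gene by gene. At this preset, splits of the samples that mix the groups called as many lists too, as given below. Members were found by name and by product, and product parts separated by semicolons were read as synonyms, so that VMP23 joined the yolk list. In each comparison the text names up to 8 genes with the largest rise and 8 with the largest fall among genes past the threshold with a mean of at least 1, an informative name and no overlap between the groups (not required for the interaction). Up to 2 members with the smallest p of each list that was called or had at least 3 members past the threshold were added, and up to 3 abundant members of each other-tissue list, and at most 2 IDs without a name in each direction. Members past the threshold of lists too short to test are named too. Of the genes this rule names, 1 is not reported here, while the counts include it.

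The fit was tested on simulated values drawn with each gene's real mean and residual spread, 5 runs with 200 genes changed among 5235; the changed genes were drawn from those above a mean log2 of 2. For TBH against WT at P2 it recovered 15.2% of genes changed by a log2 of 1, 62.7% at 2 and 81.5% at 3, with 5.5% false calls, and at P4 15.2%, 65.7% and 81.2%, with 5.1% false calls. The simulated errors were normal and independent between genes, without values listed at 0, samples that stand apart or a shift of all genes. These rates therefore hold under the assumptions of the model and may not hold for the real samples. The settings fixed in advance were quantile normalization, no filter on low values, a mean of at least 10, limma without trend, a pseudocount of 0.1, only the 2 groups compared, the replicate number as a block, sample weights, an absolute log2 change of at least 1, an estimated correlation for the lists, and each sample left out in turn. After the data were seen, 3 more were added: without WT P2 replicate 2 and TBH P4 replicate 3, only genes above 0 in all samples, and equal totals of the listed values. Quantile normalization removes differences of the whole distribution, so it is given beside the main counts where it moves the split. Whether replicate numbers pair the samples is not given in the sources used here. Computation used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.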

Results

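Ovary RNA of Bombyx mori, the domestic silkworm, was compared between animals given as WT and as TBH in the labels, at the pupal stages P2 and P4. The series describes a genetic silkworm model of hyperproteinemia, a raised protein concentration of the hemolymph, and asks which ovarian transcripts change with it. The name TBH is not spelled out in the labels. Each of the 4 groups had 3 samples. The labels state that ovaries came from 5 female pupae (n = 3), so the p-values measure the spread between these samples. The deposited values are normalized expression values (signal) whose unit is not named, so the depth in reads is unknown and no counting interval can be given. The listed values summed to between 468558.9 and 664133.6 per sample, and between 6399 and 7772 of the 15745 listed genes were above 0 in a sample. The 5235 tested genes include 641 (12.24%) with an informative name, so most of the calls counted here fall on genes without one. The gene IDs matched 0 entries of the reference name table, and no coordinates are given.

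Across genes, which are not independent replicates, the log2 values of replicates correlated at 0.838 to 0.889 among WT samples at P2, 0.914 to 0.927 among TBH samples at P2, 0.926 to 0.931 among WT samples at P4 and 0.901 to 0.938 among TBH samples at P4. WT P2 replicate 2 and TBH P4 replicate 3 stood apart from their groups. Cytosolic ribosomal protein transcripts made up 37.76% of the listed values in the first and 23.94% in the second, against group means of 29.47% ± 7.57 (SD, n = 3) in WT at P2 and 31.34% ± 6.46 in TBH at P4. WT P2 replicate 1 had the lowest share of all 12 samples (22.93%) and the most genes above 0 (7772). The corresponding means were 31.42% ± 0.95 in TBH at P2 and 34.71% ± 1.39 in WT at P4. Two-sided exact permutation tests of these shares gave p = 0.7 for TBH against WT at P2 and p = 0.7 at P4, where 3 samples against 3 cannot give a p below 0.1.

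**Figure D1:**
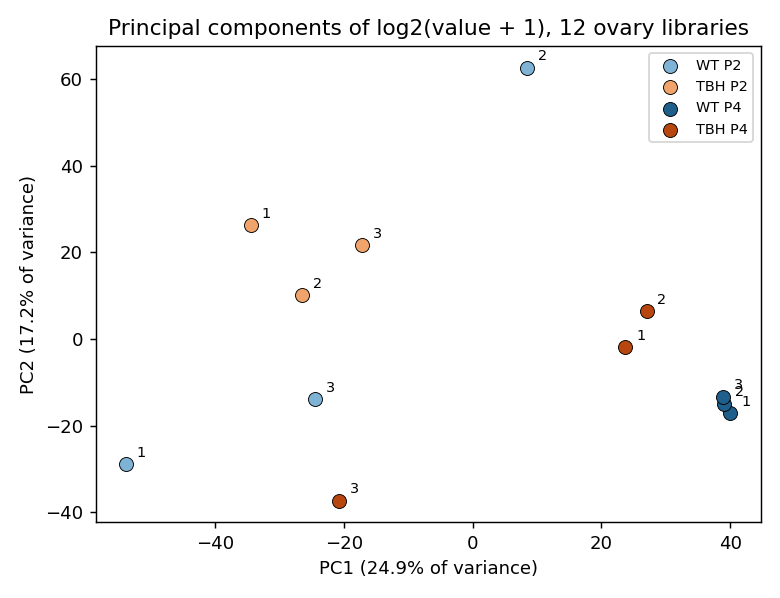
Principal components of the log2 values of the 12 libraries, 1 point per library with its replicate number; the axes give the share of the variance (24.9% and 17.2%). WT P2 replicate 2 and TBH P4 replicate 3 lie away from the other samples of their groups.

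At P2, the comparison of TBH with WT asks which transcripts differ with the line early in the pupal stage. GSTD3 (BGIBMGA002211), a glutathione S-transferase, an enzyme of a detoxifying family, stood at 105 ± 3.82 in TBH ovaries and 12.6 ± 2.91 in WT ovaries (mean ± SD, n = 3 each), an 8.34-fold difference. A beta-hexosaminidase (BGIBMGA004194), a glycosidase that removes terminal hexosamines, stood at 24.4 ± 1.55 against 0.80 ± 0.41. Cytochrome c oxidase subunit IV (BGIBMGA013680), a component of the respiratory chain, stood at 311 ± 57.4 against 114 ± 35.6, which is 2.72-fold. Vitellogenin (VG, BGIBMGA004585), the yolk protein precursor that oocytes take up, was lower in TBH, at 4.21 ± 1.18 against 62.9 ± 30.5. In the limma fit with Benjamini-Hochberg adjustment, the adjusted p was 0.002 for GSTD3 (log2 change 2.98 ± 0.36, SE), 0.00011 for the beta-hexosaminidase (3.84 ± 0.32), 0.009 for the oxidase subunit (1.47 ± 0.24) and 0.007 for VG (-3.54 ± 0.54). The 3 TBH samples lay beyond all 3 WT samples for each of them. The rule for named genes requires this, and all 78 genes called at P2 showed it. The median log2 change of all genes was -0.01 and was not subtracted; it was 0.20 without WT P2 replicate 1 and -0.22 without WT P2 replicate 2.

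Of 9 tested members of the fat body and hemolymph list, markers of another tissue, 2 rose, 1 fell and 6 did not pass at P2 (3 and 1 when adjusted over the list alone). 30K protein 14 (BGIBMGA008164) stood at 5.97 ± 1.84 in TBH against 0.43 ± 0.23 in WT (limma adjusted p = 0.009), and 30K protein 12 (BGIBMGA010876) at 28.5 ± 5.69 against 4.45 ± 2.41 (adjusted p = 0.037). Both belong to the 30K family of small hemolymph lipoproteins. SP1 (BGIBMGA011266), a storage protein of the hemolymph, stood at 0.84 ± 0.57 against 10.1 ± 7.39 (adjusted p = 0.020). The most abundant member, a 30kDa protein (BGIBMGA004454), stood at 137 ± 76.9 against 141 ± 88.8 and did not pass (adjusted p = 1.0). The list as a whole was not called (adjusted p = 0.151). Members of other-tissue lists were measured beside them. The hemocyte gene PRO-PO2 stood at 53.4 ± 10.5 in TBH against 34.7 ± 17.5 in WT, and the cuticle gene CPH44 (BGIBMGA005303) at 5456 ± 839 against 5639 ± 4484. Of the silk gland list, BCP stood at 223 ± 54.2 against 196 ± 112 and FMBP-1 at 34.1 ± 4.93 against 37.0 ± 8.99. Members joined this list by name or product, so their levels alone do not show silk gland tissue on the ovaries.

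Of the 13 tested antimicrobial peptides and immune recognition genes, 1 rose at P2 and 12 did not pass (1 when adjusted over the list alone). Cecropin B (BGIBMGA000037), a secreted antibacterial peptide, stood at 38.1 ± 23.4 in TBH, with WT samples at 5.87, 0 and 0 (limma adjusted p = 0.010). Reads from near-identical cecropin copies may have been split between them, so its level is uncertain. The list was called higher by camera (adjusted p = 0.004, median log2 change 1.02), with an adjusted p = 0.211 with an estimated correlation. This call ended without WT P2 replicate 1 (adjusted p = 0.23) or TBH P2 replicate 3 (0.064). Cytosolic ribosomal proteins were also called higher as a list (adjusted p = 0.004, median log2 change 0.23), with an adjusted p = 0.852 with an estimated correlation. In limma, 0 of its 45 tested members passed, and 1 was past an unadjusted p of 0.05. RPL30, with the smallest p among them, stood at 554 ± 113 in TBH and 352 ± 118 in WT (adjusted p = 0.437). Without WT P2 replicate 1, the ribosomal list turned the other way (adjusted p = 0.86), and its call ended also without WT P2 replicate 3 (0.99) or TBH P2 replicate 3 (0.085).

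A histone deacetylase (BGIBMGA011747), which removes acetyl groups from histones, was listed at 0 in all 3 TBH samples at P2 and at 16.7, 2.82 and 23.1 in WT (limma adjusted p = 0.008). TRAF6 (BGIBMGA001290), an adaptor of immune receptor signalling, was listed at 0 in all 3 TBH samples and stood at 8.29 ± 4.59 in WT (adjusted p = 0.021). The spliceosomal RNA U1 (ENSRNA022710950) was listed at 0 in all 3 WT samples and stood at 73.8 ± 47.6 in TBH (adjusted p = 0.029), a multi-copy gene whose level is uncertain. Without names, BGIBMGA000885 stood at 115 ± 14.4 and BGIBMGA008709 at 35.4 ± 5.67 in TBH, with WT at 0 for both (adjusted p = 2.1e-07 and 2.5e-05). BGIBMGA001432 was listed at 0 in TBH and stood at 49.9 ± 41.6 in WT (adjusted p = 0.004), and BGIBMGA003584 had TBH values of 0, 0 and 11.5 against 145 ± 96.1 (adjusted p = 0.007).

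In all, 43 genes were higher and 35 lower in TBH ovaries at P2 at a limma adjusted p under 0.05, of which 7 and 4 carry an informative name; 369 genes were past an unadjusted p of 0.05. Without both WT P2 replicate 2 and TBH P4 replicate 3, 65 were higher and 72 lower. Without TBH P2 replicate 1, 2 or 3, the counts were 28, 26 and 28 higher and 19, 20 and 21 lower, and without WT P2 replicate 1 or 3, 18 and 23 were lower. Fitted on the 6 samples of the groups alone, 15 were higher and 6 lower, and the calls of cecropin B, 30K proteins 12 and 14, the oxidase subunit, the histone deacetylase, TRAF6, SP1, BGIBMGA003584 and BGIBMGA001432 ended (adjusted p of 0.11 or more). The call of 30K protein 12 ended in 12 of 16 alternatives and that of U1 in 8 of 16, for both genes including those without any 1 of the 6 libraries (adjusted p up to 0.16 and 0.14). The calls of cecropin B and SP1 ended without TBH P2 replicate 2, that of SP1 also without TBH P2 replicate 3, and that of TRAF6 without any library except WT P2 replicate 2 (adjusted p over the alternatives up to 0.20, 0.30 and 0.12).

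**Figure D2:**
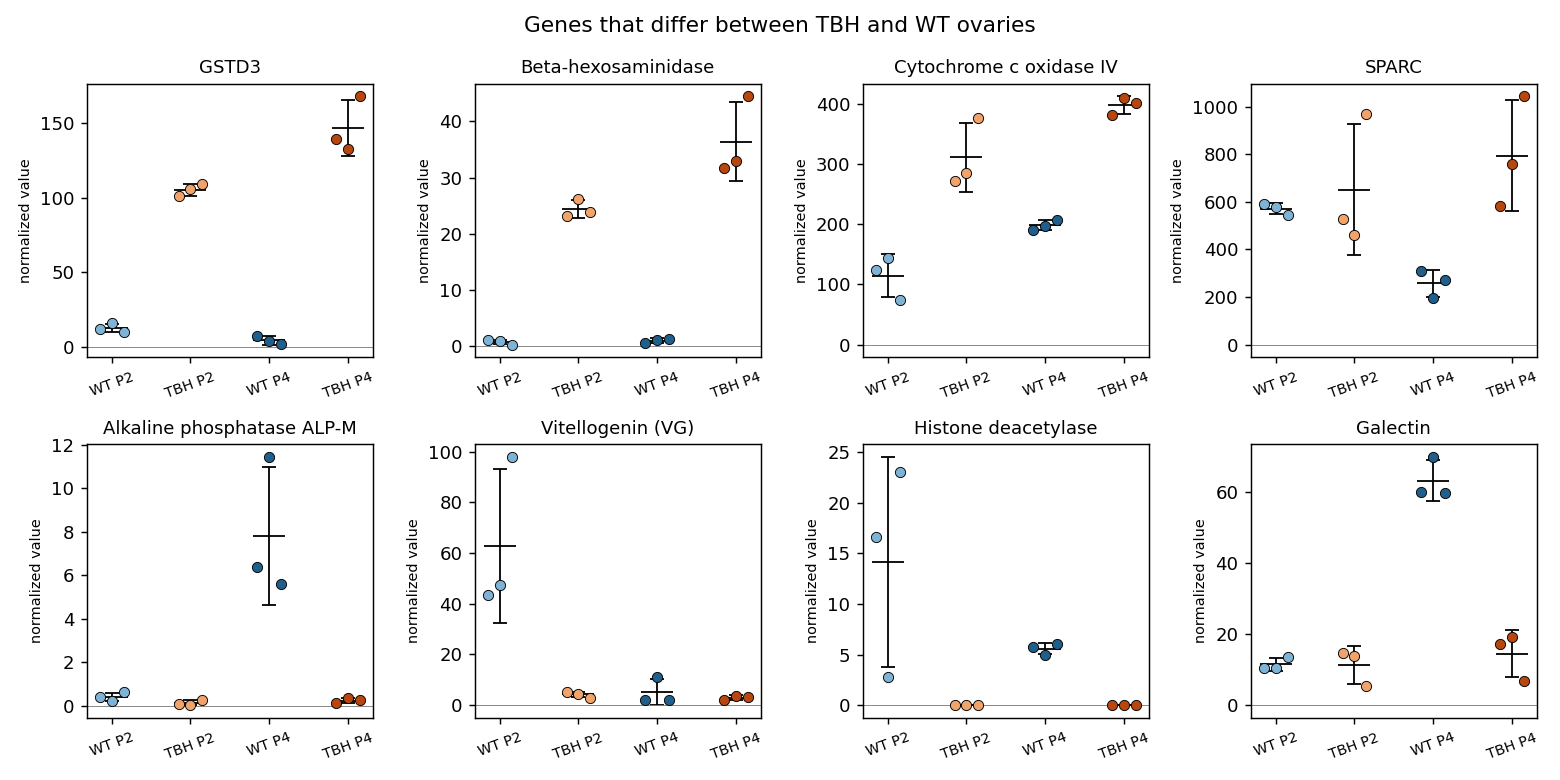
Normalized values of 8 genes in each library (points), with the group mean and SD (horizontal and vertical bars, n = 3), for the 4 groups of WT and TBH ovaries at P2 and P4. GSTD3 and the beta-hexosaminidase are higher in TBH at both stages, VG is lower in TBH at P2, and the histone deacetylase is listed at 0 in every TBH library.

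At P4, the comparison asks the same of the later stage. The log2 values of all genes shifted by a median of 0.18 between TBH and WT, and log2 changes here are given with this median subtracted, while the tests are of the unshifted difference. The median was -0.02 without TBH P4 replicate 3, 0.27 and 0.30 without TBH P4 replicate 1 or 2, and 0.26 with equal totals. GSTD3 stood at 147 ± 18.9 in TBH and 4.42 ± 2.94 in WT (33.2-fold), and the beta-hexosaminidase at 36.4 ± 7.02 against 1.04 ± 0.39. SPARC (BGIBMGA013448), a secreted protein of the extracellular matrix, stood at 795 ± 234 against 258 ± 56.8 (3.08-fold). ALP-M (BGIBMGA008818), a membrane-bound alkaline phosphatase, was lower in TBH, at 0.23 ± 0.11 against 7.81 ± 3.19, and a galectin (BGIBMGA014456), a lectin that binds galactosides, stood at 14.5 ± 6.61 against 63.2 ± 5.82. In the limma fit, the relative log2 changes were 4.73 for GSTD3 (adjusted p = 4.1e-05), 4.02 for the beta-hexosaminidase (4.2e-05), 1.42 for SPARC (0.018), -2.96 for ALP-M (0.00083) and -2.33 for the galectin (0.023).

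Of the 48 tested cuticle and trachea genes, 2 rose, 2 fell and 44 did not pass at P4, with the same counts when adjusted over the list alone (list adjusted p = 0.145). BMORCPR23 stood at 29.4 ± 3.93 in TBH against 6.58 ± 1.27 in WT (limma adjusted p = 0.012), and BMORCPR49 at 3.90 ± 1.68 with WT listed at 0 (0.007). BMORCPR75 stood at 1.45 ± 0.46 against 19.99 ± 3.39 (0.017), and BMORCPH1 had TBH samples at 0, 1.24 and 0 against 6.10 ± 1.80 (0.022). All are putative cuticle proteins of large families. The abundant cuticle gene CPH44 stood at 2401 ± 744 in TBH and 2882 ± 1160 in WT. Among members of the other-tissue lists, the 30kDa protein stood at 158 ± 67.5 against 114 ± 30.5 and PRO-PO2 at 23.7 ± 2.04 against 43.1 ± 2.52 (limma adjusted p = 0.257). BCP of the silk gland list stood at 320 ± 47.0 against 215 ± 59.3. The 2 tested muscle genes, the myosin light chain MLC-2 (BGIBMGA002259) and the actin A1 (BGIBMGA013945), stood at 309 ± 97.9 against 692 ± 88.1 and at 626 ± 147 against 1006 ± 240.4. In limma neither passed over all genes (adjusted p = 0.117 and 0.408), and 2 were lower when adjusted over the list alone.

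Of the antimicrobial list, 2 of 13 rose at P4 (4 when adjusted over the list alone), and the list was not called (adjusted p = 0.542). They were cecropin B, at 12.4 ± 3.21 in TBH with all WT samples at 0 (limma adjusted p = 0.018), and a lysozyme (BGIBMGA010439), which cleaves bacterial cell walls, at 8.04 ± 2.81 against 1.41 ± 1.54 (0.048). Translation initiation and elongation factors were called higher as a list (adjusted p = 0.030, median 0.19 above that of all genes), with an adjusted p = 0.865 with an estimated correlation and 0.12 with quantile normalization. In limma, 0 of its 20 tested members passed and 6 were past an unadjusted p of 0.05. Subunit 2 of initiation factor eIF2 (BGIBMGA001437), with the smallest p among them, stood at 156 ± 24.6 against 80.8 ± 13.9 (adjusted p = 0.102), and TEF2 at 620.5 ± 23.7 against 211 ± 191 (0.192). A beta subunit of the chaperonin CCT (BGIBMGA001206), which folds actin and tubulin, had TBH samples at 0, 0.42 and 2.10 against 17.1 ± 7.03 in WT (adjusted p = 0.042). The histone deacetylase was again listed at 0 in all 3 TBH samples, against 5.61 ± 0.54 (0.034). Without names, BGIBMGA003014 stood at 570.1 ± 123 against 4.85 ± 4.36 (0.00021) and BGIBMGA000885 at 80.4 ± 17.8 with WT at 0 (5.0e-07). BGIBMGA010030 was listed at 0 in TBH against 244 ± 48.0 (0.018), and BGIBMGA012753 had TBH samples at 2.91, 2.96 and 0 against 94.5 ± 16.2 (0.002).

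At P4, 59 genes were higher and 42 lower in TBH at a limma adjusted p under 0.05 (614 at an unadjusted p of 0.05), 8 and 6 of them with an informative name. With sample weights, 257 were higher and 202 lower. With quantile normalization, 60 were higher and 79 lower, so that the share higher went from 58.4% to 43.2%. Higher were 34 without WT P4 replicate 2, 35 without TBH P4 replicate 2 and 38 without TBH P4 replicate 3. Lower were 16, 17 and 22 without WT P4 replicate 1, 2 or 3, and 24 and 25 without TBH P4 replicate 1 or 2. The call of the lysozyme ended in 13 of 17 alternatives, among them those without any 1 library except WT P4 replicate 1, and those of the chaperonin subunit, BMORCPR75, the histone deacetylase and BGIBMGA010030 ended without any 1 of the 6 libraries (adjusted p over the alternatives up to 0.18, 0.18, 0.082, 0.12 and 0.082). Those of the galectin and BMORCPH1 ended without any library except TBH P4 replicate 2 (up to 0.12 for each), that of cecropin B without any except TBH P4 replicate 3 (up to 0.083), that of BMORCPR23 without WT P4 replicate 1 or 2 or TBH P4 replicate 1 or 2 (up to 0.075), and that of SPARC without WT P4 replicate 2 or 3 or TBH P4 replicate 2 or 3 (up to 0.11).

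In WT ovaries, the comparison of P4 with P2 asks how the ovary changes over these stages. The median log2 change of all genes was -0.42, and log2 changes here are given with it subtracted, while the tests are of the unshifted difference. The median was -0.21 without WT P2 replicate 1, -0.65 without WT P2 replicate 2 and -0.02 with quantile normalization. VMP23 (BGIBMGA006755), a vitelline membrane protein of the eggshell, stood at 784 ± 371 at P4 against 10.7 ± 2.34 at P2, a 73.5-fold difference. MLC-2, the regulatory light chain of myosin, stood at 692 ± 88.1 against 189 ± 95.3 (3.66-fold), and muscle actin A1 at 1006 ± 240.4 against 383 ± 156 (2.63-fold). The cuticle protein gene CPG43 (BGIBMGA011713) stood at 3012 ± 1739 at P2, with samples at 0, 15.9 and 3.85 at P4. VG stood at 5.03 ± 5.11 at P4 against 62.9 ± 30.5 at P2. In the limma fit the relative log2 changes were 6.42 for VMP23 (adjusted p = 1.7e-06), 2.41 for MLC-2 (0.006), 1.87 for A1 (0.023) and -3.20 for VG (0.002), and the adjusted p was 0.00043 for CPG43.

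The nervous system list, markers of another tissue, held 9 tested genes, of which 7 fell in WT and 2 did not pass (7 when adjusted over the list alone), and camera called it lower (adjusted p = 6.9e-12, median 5.25 log2 units under that of all genes, which is -5.25). This camera call held with an estimated correlation (adjusted p = 0.041). Of the 9 tested genes, 8 were neuropeptide-like 4 genes, so the call describes this family and not nervous tissue as a whole. Its members that fell were annotated as neuropeptide-like 4 genes, and 1 of them (BMORCPH27, 4A) is annotated as a cuticle protein too. They are near-identical family members that may share reads, so single levels are uncertain. At P2 they stood at 430.1 ± 341 (BMORCPH27), 205 ± 134 (4C, BGIBMGA011718), 91.1 ± 51.9 (4E, BGIBMGA011764), 72.3 ± 30.6 (4F, BGIBMGA011769) and 53.6 ± 25.3 (4B, BGIBMGA011716), and all 5 were listed at 0 in the WT samples at P4 (limma adjusted p from 1.2e-06 to 9.6e-05). A second 4B gene (BGIBMGA011763) stood at 110.1 ± 16.0 at P2 and at 15.3, 0 and 0 at P4 (0.004). Of the 48 cuticle and trachea genes, 2 rose, 5 fell and 41 did not pass (2 and 6 when adjusted over the list alone), and the list was not called (adjusted p = 0.966). BMORCPR26 stood at 12.2 ± 1.54 at P4 against 1.40 ± 1.23 at P2 (0.011), and the abundant CPH44 at 2882 ± 1160 against 5639 ± 4484 (0.366).

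Of the 9 fat body and hemolymph genes, 2 fell in WT and 7 did not pass (5 when adjusted over the list alone), with the list called lower (adjusted p = 0.026; adjusted p = 0.357 with an estimated correlation). The list call ended without WT P2 replicate 2 (0.17) or 3 (0.18). SP1 stood at 0.20 ± 0.07 at P4 against 10.1 ± 7.39 at P2 (limma adjusted p = 0.002), and SP2 had P4 samples at 0.12, 0 and 0.09 against 2.33 ± 0.49 (0.031). The 30kDa protein stood at 114 ± 30.5 against 141 ± 88.8 (0.931), and PRO-PO2 at 43.1 ± 2.52 against 34.7 ± 17.5 (0.460). Of 29 protein folding and heat shock genes, 1 rose, 3 fell and 25 did not pass (1 and 12 when adjusted over the list alone; list adjusted p = 0.079). A small heat shock protein (BGIBMGA005781) stood at 42.4 ± 6.39 against 487 ± 278 (0.00025), and FKBP12, a prolyl isomerase, at 235 ± 46.2 against 512 ± 101 (0.009).

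Of 20 translation factors, 2 fell in WT and 18 did not pass (8 when adjusted over the list alone; list lower, adjusted p = 0.006; adjusted p = 0.383 with an estimated correlation). The list call ended without WT P2 replicate 2 (0.11). The members were subunit K of initiation factor eIF3 (BGIBMGA010671), at 116 ± 10.8 against 252 ± 46.1 (limma adjusted p = 0.037), and its subunit J (BGIBMGA004175), at 74.2 ± 0.55 against 214 ± 75.8 (0.047). Of 8 peptidases and inhibitors, 1 fell and 7 did not pass (4 when adjusted over the list alone; list lower, adjusted p = 0.026; adjusted p = 0.357 with an estimated correlation), a Kazal-type proteinase inhibitor (BGIBMGA011573) at 11.2 ± 8.28 against 220.1 ± 134 (0.003). This list call ended without WT P2 replicate 2 (0.11) or WT P4 replicate 3 (0.067). SERPIN-1 stood at 4.99 ± 0.60 against 23.1 ± 13.7 and did not pass (0.072). Cytosolic ribosomal proteins were called higher as a list relative to all genes (adjusted p = 3.3e-05, median 0.67 above that of all genes; adjusted p = 0.773 with an estimated correlation). Of their 45 members, 1 fell and 44 did not pass, with 1 when adjusted over the list alone. UBI1, a fusion of ubiquitin with ribosomal protein L40 whose reads other ubiquitin genes may share, stood at 785 ± 97.9 against 1884 ± 139 (0.002), and RPL10 at 6638 ± 601 against 3989 ± 1637 (0.134). The ribosomal call ended with quantile normalization (adjusted p = 0.62), without WT P2 replicate 1 (0.13) and without WT P2 replicate 3 (0.18).

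Further genes that rose in WT were ALP-M (7.81 ± 3.19 at P4 against 0.40 ± 0.19 at P2, limma adjusted p = 0.00068), the galectin (63.2 ± 5.82 against 11.6 ± 1.83, 0.008), a histone H2A (163 ± 32.3 against 31.4 ± 12.4, 0.00026), the small nucleolar RNA U3 (506 ± 239 against 108 ± 45.1, 0.018) and U1 (109 ± 90.9, with P2 samples at 0, 0.011). Histone H2A, U3 and U1 are multi-copy genes, so their levels are uncertain. The lysozyme stood at 1.41 ± 1.54 at P4 against 119 ± 47.9 at P2 (2.5e-05). Without names, BGIBMGA004157 took 9.17% ± 2.64 of the listed values at P4 and 0.28% ± 0.17 at P2 (54081 ± 17528 against 1406 ± 682, 5.9e-06), a two-sided exact permutation p of 0.1 for the share, the smallest that 3 samples against 3 allow. BGIBMGA014404 stood at 108 ± 12.6 at P4 with P2 at 0 (0.001). BGIBMGA002626 was listed at 0 at P4 against 146 ± 73.7 at P2 (1.4e-05), and BGIBMGA010977 had P4 samples at 0, 0.19 and 0.17 against 145 ± 93.7 (3.9e-06).

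In WT, 53 genes were higher and 162 lower at P4 at a limma adjusted p under 0.05 (1174 at an unadjusted p of 0.05), 11 and 48 of them with an informative name. With sample weights, 102 were higher and 376 lower, and without both WT P2 replicate 2 and TBH P4 replicate 3, 153 and 1037. With quantile normalization, 111 were higher and 85 lower, so that the share higher went from 24.7% to 56.6%. Without WT P2 replicate 2, 96 were higher and 424 lower, and without WT P4 replicate 1, 2 or 3 the counts were 31, 26 and 32 higher and 93, 83 and 85 lower. Without WT P2 replicate 1 or 3, 104 and 263 were lower. Fitted on the 6 samples alone, 25 were higher and 47 lower, and among others the calls of MLC-2, VG, SP1, ALP-M and the Kazal inhibitor ended (adjusted p of 0.054 or more). Quantile normalization ended the calls of SP2 and both eIF3 subunits. SP2 and BGIBMGA010671 each lost the call in 9 alternatives and BGIBMGA004175 in 12, among them those without WT P2 replicate 1 or any WT P4 replicate (adjusted p up to 0.12, 0.12 and 0.15); SP2 and BGIBMGA004175 lost it also without WT P2 replicate 3. The call of A1 ended without WT P2 replicate 1 or any WT P4 replicate (up to 0.12), that of U3 without WT P2 replicate 1 or WT P4 replicate 2 or 3 (up to 0.12), that of U1 without WT P4 replicate 1 or 2 (up to 0.058), that of BMORCPR26 without WT P4 replicate 2 (up to 0.074) and that of FKBP12 without WT P4 replicate 2 or 3 (up to 0.093).

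**Figure D3:**
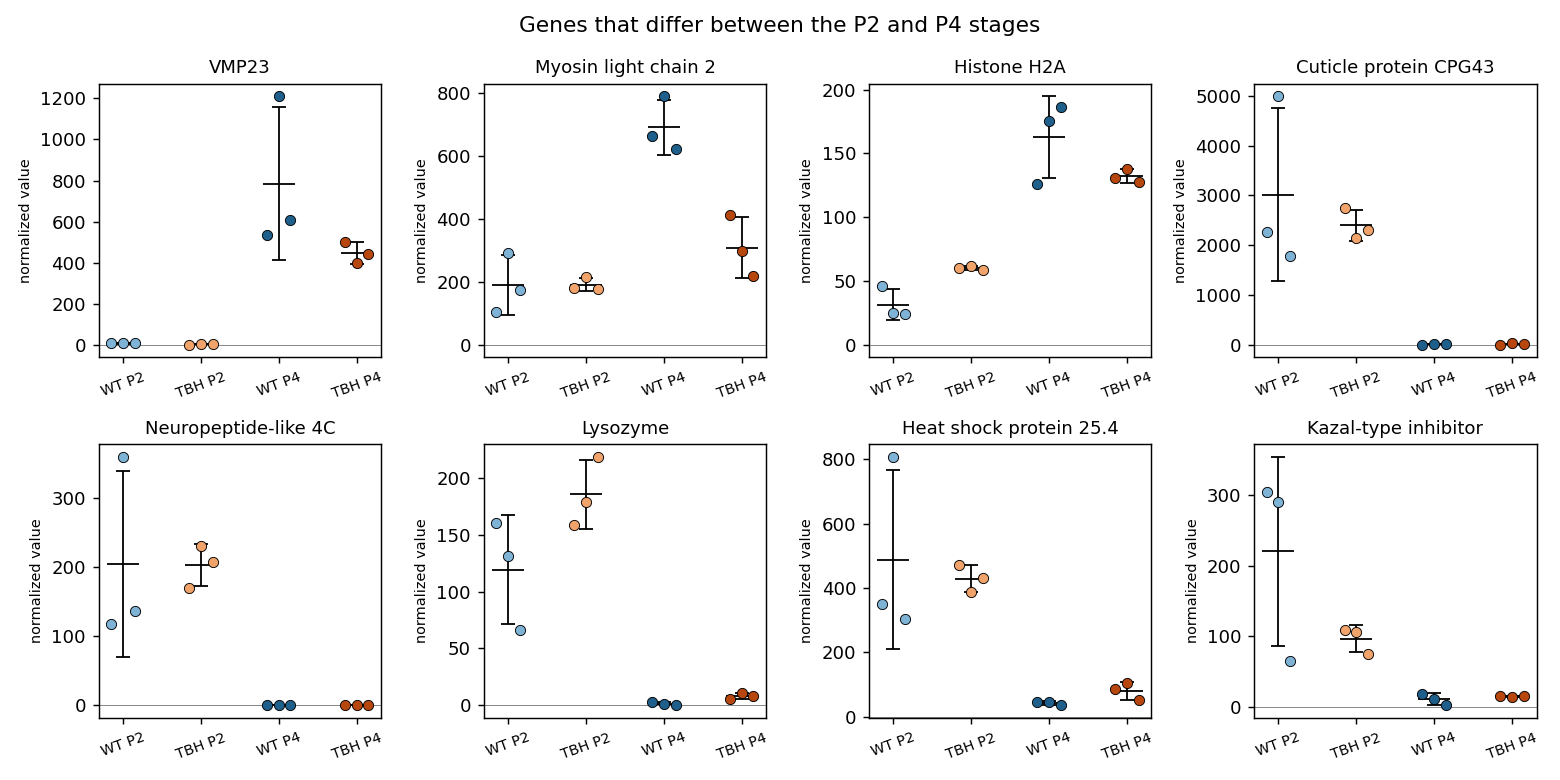
Normalized values of 8 genes in each library (points), with the group mean and SD (horizontal and vertical bars, n = 3), for WT and TBH ovaries at P2 and P4. VMP23 is higher at P4 in both lines, and CPG43, neuropeptide-like 4C, the lysozyme and the small heat shock protein are lower at P4 in both.

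In TBH ovaries, the same comparison of the stages had a median log2 change of all genes of -0.21. Log2 changes here are given with it subtracted, while the tests are of the unshifted difference. The median was -0.41 without TBH P4 replicate 3, -0.13 without TBH P4 replicate 1 or 2 and -0.01 with quantile normalization. VMP23 stood at 449 ± 51.8 at P4 against 4.87 ± 1.69 at P2, 92.1-fold. CPG43 stood at 2398 ± 319 at P2, with P4 samples at 0, 21.7 and 5.92. Cecropin D (CECD), an antibacterial peptide, stood at 44.59 ± 32.02 at P2 and was listed at 0 in all P4 samples. In the limma fit the relative log2 change was 6.50 for VMP23 (adjusted p = 1.5e-06), and the adjusted p was 0.001 for CPG43 and 0.00017 for CECD.

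Of the 9 genes of the nervous system list, 8 fell in TBH and 1 did not pass (8 when adjusted over the list alone). Camera called the list lower (adjusted p = 4.7e-23, and 0.005 with an estimated correlation), its median being -5.81 relative to all genes. As 8 of its tested genes are neuropeptide-like 4 genes, this call too describes that family. Neuropeptide-like 4C stood at 203 ± 30.6, 4F at 75.9 ± 48.2 and the 4B genes at 48.2 ± 30.3 (BGIBMGA011716) and 92.3 ± 47.7 (BGIBMGA011763) at P2, and all were listed at 0 at P4 (limma adjusted p from 1.5e-06 to 0.003). BMORCPH27 stood at 423 ± 54.1 at P2 and at 0, 5.12 and 0 at P4 (5.7e-05), and 4E at 104 ± 10.3 and at 0, 0.84 and 0 (6.0e-06). Of 48 cuticle and trachea genes, 2 rose, 4 fell and 42 did not pass (2 and 5 when adjusted over the list alone; list adjusted p = 0.849). BMORCPR26 stood at 11.1 ± 5.83 at P4, with P2 samples at 0, 1.01 and 0 (0.005), and BMORCPR49 at 3.90 ± 1.68, with P2 samples at 0, 0 and 0.87 (0.016).

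Of the 9 fat body and hemolymph genes, 3 fell in TBH and 6 did not pass (5 when adjusted over the list alone), and the list was called lower (adjusted p = 3.9e-05; adjusted p = 0.038 with an estimated correlation). 30K protein 12 stood at 2.41 ± 2.42 at P4 against 28.5 ± 5.69 at P2 (limma adjusted p = 0.006), and 30K protein 14 at 0.58 ± 0.69 against 5.97 ± 1.84 (0.009). The 30kDa protein stood at 158 ± 67.5 against 137 ± 76.9 (0.908), and PRO-PO2 at 23.7 ± 2.04 against 53.4 ± 10.5 (0.115). Of the 13 antimicrobial genes, 4 fell and 9 did not pass (5 when adjusted over the list alone; list lower, adjusted p = 0.008; adjusted p = 0.137 with an estimated correlation), among them CECD and the lysozyme, at 8.04 ± 2.81 against 186 ± 30.6 (0.00024). The list call ended without TBH P2 replicate 3 (0.14) or TBH P4 replicate 3 (0.31). Of 8 peptidases and inhibitors, 1 fell and 7 did not pass (2 when adjusted over the list alone; list lower, adjusted p = 0.040; adjusted p = 0.295 with an estimated correlation). SERPIN-1, an inhibitor of serine proteases, stood at 6.26 ± 3.71 against 46.5 ± 1.46 (0.014), and the Kazal inhibitor at 15.1 ± 0.93 against 96.9 ± 18.6 (0.089). The call of the peptidase list ended without TBH P2 replicate 3 (0.11) or TBH P4 replicate 3 (0.088). Without names, BGIBMGA003014 stood at 570.1 ± 123 against 5.63 ± 3.30 (0.00022) and BGIBMGA004157 at 46112 ± 13652 against 1003 ± 186 (6.0e-06). BGIBMGA002565 stood at 7.92 ± 8.17 against 1452 ± 329 (0.00059), and BGIBMGA012410 was listed at 0 at P4 against 94.2 ± 18.1 (6.0e-06).

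In TBH, 19 genes were higher and 70 lower at P4 at a limma adjusted p under 0.05 (565 at an unadjusted p of 0.05), 4 and 28 of them with an informative name. With sample weights, 135 were higher and 798 lower, and without both WT P2 replicate 2 and TBH P4 replicate 3, 29 and 145. The weights were 0.61, 2.795 and 1.305 for TBH P2 replicates 1, 2 and 3. They were 3.719, 1.213 and 0.311 for those at P4, so the weighted counts lean on few libraries. With quantile normalization, 38 were higher and 55 lower, so that the share higher went from 21.3% to 40.9%. Higher were 8 without TBH P2 replicate 1 and 8 without replicate 2, and 7 and 12 without TBH P4 replicate 1 or 2, and without TBH P2 replicate 2, 46 were lower. The call of BMORCPR49 ended without TBH P2 replicate 1 or 2 (adjusted p over the alternatives up to 0.13), and that of SERPIN-1 without any TBH P2 replicate (up to 0.064). With only the 2 groups compared, the calls of 30K protein 12 (adjusted p = 0.050) and 30K protein 14 (0.095) ended, and that of 30K protein 14 also ended with a pseudocount of 0.1 (0.071).

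The difference of the TBH effect between the stages was tested as an interaction. In the limma fit, 6 genes were higher and 9 lower in the TBH effect at P4 than at P2 at an adjusted p under 0.05. Past an unadjusted p of 0.05 were 269 of 5235 genes, about as many as that threshold lets through without any change. Of the 15 genes called, 1 has an informative name, U1. It stood at 73.8 ± 47.6 in TBH at P2, 109 ± 90.9 in WT at P4, at 0 in WT at P2 and at 0, 0 and 24.1 in TBH at P4 (adjusted p = 0.022). With sample weights, 17 were higher and 16 lower, and without both WT P2 replicate 2 and TBH P4 replicate 3, 2 and 5. Leaving out 1 library gave 3 higher without WT P2 replicate 1, TBH P2 replicate 2, WT P4 replicate 1 or 2, or TBH P4 replicate 2, and 1 to 5 lower without any library except WT P2 replicate 1, TBH P2 replicate 3 and TBH P4 replicate 3. The call of U1 ended in 11 alternatives, among them those without any 1 library of the 12 except TBH P2 replicate 1, WT P4 replicate 3 and TBH P4 replicate 3 (adjusted p up to 0.095). Among genes without a name, BGIBMGA003014 stood at 570.1 ± 123 in TBH at P4 and at 5.18 ± 1.88, 5.63 ± 3.30 and 4.85 ± 4.36 in WT at P2, TBH at P2 and WT at P4 (adjusted p = 0.010). GSTD3, VG, SPARC, ALP-M and the galectin were not past the threshold in this test, so a larger effect at 1 stage is not shown for them. Cytosolic ribosomal proteins were called lower as a list (adjusted p = 1.7e-06, median -0.60 relative to all genes; adjusted p = 0.762 with an estimated correlation), with 0 of 45 members past the limma threshold and 0 past an unadjusted p of 0.05. Its call ended without WT P2 replicate 1 (0.13), without TBH P4 replicate 3 (0.35) and with quantile normalization (0.31). The median of all genes was 0.19 here, and it was -0.03 without WT P2 replicate 1, 0.40 without WT P2 replicate 2, 0.12 without TBH P2 replicate 3, 0.30 without TBH P4 replicate 2 and -0.02 without TBH P4 replicate 3.

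The calls of TBH against WT at P2 and P4, which share no libraries, were compared. Higher in TBH at both stages were 23 genes and lower at both 13, and 0 genes were called in opposite directions. Independent calls would share 0.48 and 0.28. Both comparisons use the same estimate of each gene's spread, so their calls are not fully independent and these expectations may be too low. Of these 36 genes, 4 have an informative name: GSTD3, the beta-hexosaminidase, cecropin B and the histone deacetylase. None of the 36, a count of 0, was also called in the limma test of the difference between the stages. That test called 15 of 5235 genes, and the 36 were picked for the same direction at both stages. A count of 0 was therefore likely in advance and says little. Across the 5235 genes, which are not independent replicates, the log2 changes at the 2 stages had a Pearson r of 0.36 and a covariance of 0.240. Fitted on the 6 samples of each comparison alone, 9 genes were shared, and without TBH P2 replicate 2, 21. Lower at both stages were 23 without WT P2 replicate 2, and 6 to 8 without TBH P2 replicate 1 or 2, any WT P4 replicate, or TBH P4 replicate 1 or 2.

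**Figure D4:**
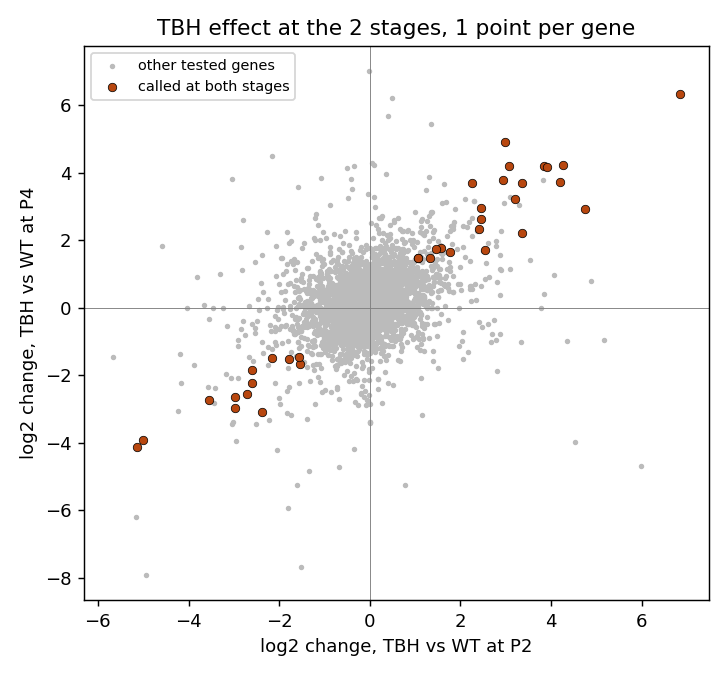
Log2 change of TBH against WT ovaries at P2 (horizontal axis) and P4 (vertical axis), 1 point per tested gene. The 36 genes called at both stages lie at the upper right (23) and the lower left (13).

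Lists with fewer than 5 tested members were described gene by gene. VIG, a vasa intronic gene and the 1 tested member of the germline list, stood at 2125 ± 210 in WT at P2, 1919 ± 361 in TBH at P2, 1843 ± 252 in WT at P4 and 1749 ± 114 in TBH at P4. VIG joined this list by its product, which alone does not make it a germline marker. A single gene also cannot show whether the germline content changed. Of the yolk list, VG and VMP23 are given above. The chorion list held the transcription factors CBZ (15.8, 0 and 10.6 in WT at P2, then 8.01 ± 3.84, 1.09 ± 1.43 and 10.4 ± 6.44 in the same order) and C/EBP (5.61, 0 and 4.12 in WT at P2, 0.77 ± 0.53 in TBH at P2, 3.34 ± 2.23 in WT at P4, and 0, 0 and 2.27 in TBH at P4). The muscle list held MLC-2 and A1, the hemocyte list PRO-PO2, and the silk gland list BCP, FMBP-1, P25 and FIBL, of which FIBL stood at 0.98 ± 0.49 and P25 at 1.78 ± 0.79 in WT at P2. In the autophagy list, ATG8 fell in WT from 525 ± 137 at P2 to 234 ± 9.36 at P4 (limma adjusted p = 0.028), a call that ended in 9 alternatives, among them quantile normalization and those without WT P2 replicate 1 or any WT P4 replicate (up to 0.11), and ATG3 stood at 8.26 ± 8.70 in WT at P2. The hemolymph juvenile hormone binding protein HJHBP stood at 3.37 ± 1.36 in WT at P2, with WT samples at 0, 0 and 0.47 at P4 (0.037, ended in 9 alternatives, among them the same settings, up to 0.14). In the ecdysteroid lists, the 16 kDa protein (BGIBMGA008405) stood at 173 ± 72.1 in WT at P2, 186 ± 13.3 in TBH at P2, 200.4 ± 13.4 in WT at P4 and 247 ± 54.8 in TBH at P4. In the same order, CYP306A1 stood at 7.79 ± 0.66, 11.6 ± 0.87, 7.30 ± 1.45 and 6.94 ± 1.43, and DIB at 4.78 ± 1.22, 2.29 ± 1.70, 9.60 ± 2.49 and 3.90 ± 1.97 (limma adjusted p = 0.299 for DIB in TBH against WT at P4). In the DNA repair list RAD23 stood at 126 ± 38.6 in WT at P2 and 55.9 ± 7.27 at P4 (0.054), in the apoptosis list survivin-2 at 29.8 ± 10.5 and 22.2 ± 4.47 (0.678), and in the signalling list (Notch, EGFR, Hedgehog, Wnt and TGF-beta) TINP1 at 195 ± 57.5 and 119 ± 14.5 (0.156). In the limma fit, the other members of these lists did not pass in the comparisons of lines or stages.

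The lists that were tested and not called in any comparison are given by their smallest adjusted p over the 4 comparisons of lines and stages. These were 0.450 for insulin and TOR signalling, 0.673 for the cell cycle and DNA replication, 0.450 for the proteasome, 0.334 for oxidative phosphorylation, 0.480 for glycolysis and the citric acid cycle, 0.480 for lipid metabolism and transport, 0.669 for amino acid, urea and purine nitrogen metabolism, 0.450 for antioxidant and detoxification enzymes, 0.300 for the extracellular matrix and cell adhesion, 0.145 for cuticle and trachea and 0.066 for protein folding. Of the 19 antioxidant and detoxification genes, GSTD3 was the 1 member past the limma threshold in TBH against WT at each stage.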

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

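The interaction, its gene lists and the alternatives were set in advance, apart from 3 alternatives added later. Of the split counts and the tests of explanations, those for the lists of the interaction and for failed estimates among genes at 0 in 1 line were set before their results were seen, the others after. The difference of the TBH effect between P2 and P4, tested in the limma interaction, called 6 genes higher and 9 lower at an adjusted p under 0.05. Of the named and single genes the fitted log2 difference was -10.69 for U1, -6.13 for BGIBMGA008709, 7.02 for BGIBMGA003014, 5.28 for BGIBMGA003964 and -4.35 for BGIBMGA009543. U1, BGIBMGA008709 and BGIBMGA003964 have a group with all samples listed at 0, and BGIBMGA009543 has single samples at 0. With a pseudocount of 0.1 the values of these 4 genes were -16.19, -9.64, 8.56 and -8.69, and that of BGIBMGA003014 was 7.69, so the sizes depend on the pseudocount. The call of U1 ended in 11 of 21 alternatives, that of BGIBMGA009543 in 16 of 20 and that of BGIBMGA003014 in 2 of 22. The ribosomal protein list had a median log2 difference of -0.41 and was called lower. Its call ended without WT P2 replicate 1 (adjusted p = 0.13), without TBH P4 replicate 3 (0.35), with quantile normalization (0.31) and with an estimated correlation (0.76).

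Of 100 combinations of splits of the samples, 3 gave as many called genes in the interaction as the real 15 (the highest other gave 20). The 2 others, with 17 and 20, kept the real lines at P4 and mixed them at P2, so an effect at 1 stage alone can give as many. These combinations therefore do not decide whether chance explains the calls. The 1 list called in the interaction was reached by 82 of 100 combinations (highest other 7), so chance is not excluded for it. The 36 genes shared by the TBH effects at both stages were reached by 1 of 100 combinations, the real one (highest other 1). At P4 the other splits call at most 1 gene, which bounds what they can share, so the combinations alone decide little. The 2 comparisons share no libraries, though, and of the genes called in both, 36 had the same direction and 0 the opposite. This argues against chance for the sharing. Independent calls would share 0.48 higher and 0.28 lower, against 23 and 13. Both comparisons use the same estimate of each gene's spread, so genes of low spread pass more easily in both. These expectations may therefore be too low. With only the 2 groups compared, fewer genes were shared, as given above. With 3 samples against 3 there are 10 splits, too few for a share under 0.05. In them the real split gave 78 genes for TBH against WT at P2 (highest other 14), 101 at P4 (highest other 1), 215 for the stages in WT (highest other 1) and 89 in TBH (highest other 3), each reached by 1 split. For the lists the real split gave 2, 1, 5 and 4 (highest other 7, 5, 5 and 5), reached by 7, 10, 2 and 5 of the 10 splits. In each of these comparisons a wrong split thus called as many lists or more at the preset correlation. Chance is therefore not excluded for these numbers of called lists.

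A lower VG and SP1 with higher 30K proteins 12 and 14 in TBH ovaries at P2 may come from fat body left on the ovaries. A different amount of it would move these transcripts the same way. The 30K genes did not all rise. The abundant 30kDa protein did not pass at P2, and LP, a 30 kDa lipoprotein gene, had a lower mean in TBH without being called. The log2 change of 30K protein 12 minus that of SP1 was 4.99 (SE 0.69, errors taken as independent). Both genes were chosen because they moved apart, so this is no independent test, and a different amount of fat body is not excluded by it. The call of 30K protein 12 ended in 12 of 16 alternatives. A fat body whose own expression differs in TBH stays open, as does a change in the ovary itself, and neither was tested.

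The fall of neuropeptide-like 4 and CPG43 transcripts from P2 to P4 may come from cuticle-forming tissue left on the ovaries at P2. The other 6 cuticle genes with a mean of at least 10 at P2 had a median log2 change of -0.58 in WT (range -2.39 to -0.01) and -1.22 in TBH (range -3.30 to 0.68), and 1 of the 6 fell past the threshold in TBH. The limit of 10 left out less abundant cuticle genes that were called lower, so cuticle-forming tissue is not excluded. Reads moved between family members would keep their sum, which at P4 was 0.52% of that at P2 in WT (5.1 against 975.9) and 0.20% in TBH (2.0 against 990.8). Tested members were listed at 0 in 93.8% of values at P4 and 4.2% at P2, 89.6 percentage points more. Failed estimates that are as frequent at both stages would not give this. These zeros are the fall itself, however, so failures that depend on the stage are not excluded. A tissue rich in CPG43 and neuropeptide-like 4 stays open, as does a change of the ovary with the stage, untested.

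Listed at 0 in all 6 libraries of 1 line and above 1 in all 6 of the other were 9 genes, 3 at 0 in TBH and 6 at 0 in WT, 1 of them with a name, the histone deacetylase. Failed estimates without regard to line or stage may give such genes in any split. The libraries were split 100 times into 6 and 6, the other splits mixing the lines, with the split by stage left out. Of these, 1 gave as many, the real one (highest other 1), which argues against failures without regard to line and stage. The split by stage, which was left out, mixes the lines too. It gave 7 genes at 0 at P4 and 2 at 0 at P2, so such genes are not particular to the lines. A sequence or copy number variant of 1 line against the reference and a change of expression cannot be told apart for these 9 genes, since deciding it needs reads or a genome.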

How the results depend on the processing

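The alternatives without 2 libraries that stand apart, with only genes above 0 in all samples and with equal totals were chosen after seeing the data; the others were planned. Of 100 named calls, 53 kept their direction and side of the threshold in all alternatives, 47 lost the call in at least 1, and 0 turned direction. Of 46 named genes that were not called, 10 passed in some alternative, and a sign that changed while a gene stayed uncalled is not counted. The cause of changed counts was not tested, apart from fewer genes or samples in the fit where stated. Depth limits are unknown, since no reads are given in the sources used here. Under the fold minimum and in limma without trend every count stayed within 1.5 times the main one.

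Counts below are those that moved by over 1.5 times, from main values of 43 higher and 35 lower for TBH against WT at P2, 59 and 42 at P4, 53 and 162 for the stages in WT, 19 and 70 in TBH, 6 and 9 in the interaction, an overlap of 36 (23 higher, 13 lower), and 2, 1, 5, 4 and 1 lists. With a mean of at least 10, fewer genes were tested, and there were 19 higher and 10 lower at P2, 18 lower at P4, 2 lower in the interaction, an overlap of 21 (14 higher, 7 lower), 2 lists at P4 and 2 for WT stages. With only the 2 groups compared, 15 higher and 6 lower at P2, 25 higher and 47 lower for WT stages, and an overlap of 9 (7 higher, 2 lower). Without filter on low values, 23 lower at P2, 97 lower for WT stages, 3 lower in the interaction and 4 lists at P2. With a pseudocount of 0.1, 5 lower in the interaction. With quantile normalization, 79 lower at P4, 111 higher and 85 lower for WT stages, 38 higher for TBH stages, 0 lists at P4 and 0 in the interaction. With sample weights, 257 higher and 202 lower at P4, 102 and 376 for WT stages, 135 and 798 for TBH stages, and 17 and 16 in the interaction. These weights were estimated from the same data. They ran from 0.194 for WT P2 replicate 2 to 3.719 for TBH P4 replicate 1, so libraries count unequally in these numbers. Without the 2 libraries, 65 higher and 72 lower at P2, 153 and 1037 for WT stages, 29 and 145 for TBH stages, 2 and 5 in the interaction, 24 lower in the overlap, and 5 lists at P2, 2 at P4, 2 for WT stages and 2 in the interaction. With only genes above 0 in all samples, 17 higher and 11 lower at P2, 37 higher at P4, 2 and 2 in the interaction, an overlap of 18 (12 higher, 6 lower), 3 lists at P4 and 0 for TBH stages. With equal totals, 7 lower in the overlap and 2 lists in the interaction. With an estimated correlation, 0 lists at P2, 0 at P4, 1 for WT stages, 2 for TBH stages and 0 in the interaction.

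With the replicate number as a replicate block, 28 were higher at P2, 98 lower for WT stages, 9 higher for TBH stages and 4 lower in the interaction. Same-numbered samples did not deviate together (correlations of -0.176 to 0.065 across genes), so the numbers are not taken to pair the samples.

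Leaving out each library in turn, counts ranged from 26 to 42 higher and 18 to 42 lower at P2, 34 to 48 and 16 to 29 at P4, 26 to 96 and 83 to 424 for WT stages (424 without WT P2 replicate 2), 7 to 14 and 46 to 68 for TBH stages, and 3 to 7 and 1 to 8 in the interaction. The overlap ranged from 21 to 46 (15 to 23 higher, 6 to 23 lower). The lists ranged from 0 to 6 at P2, 1 to 3 at P4, 2 to 6 for WT stages, 2 to 4 for TBH stages and 0 to 4 in the interaction.

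The list cytosolic ribosomal proteins, TBH vs WT at P2, had an adjusted p from 1.7e-18 without WT_P2 replicate 2 to 0.99 without WT_P2 replicate 3. It turned lower without WT_P2 replicate 1 (adjusted p = 0.86).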

Other observations

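The genes of this paragraph were chosen after their values were seen. IGFLP (BGIBMGA012305), an insulin-like growth factor-like peptide, fell from P2 to P4 in both lines, from 3752 ± 2337 to 323 ± 19.4 in WT and from 1345 ± 497 to 105 ± 50.4 in TBH (mean ± SD, n = 3; limma adjusted p = 0.002 and 0.001). BMPP (BGIBMGA014551), the precursor of paralytic peptide, an insect cytokine, fell from 25.5 ± 8.32 to 0.81 ± 1.20 and from 47.4 ± 12.1 to 0.79 ± 0.44 (0.00042 and 0.00017). The 30 kDa lipoprotein gene LP (BGIBMGA004394) fell from 45.5 ± 26.8 to 1.80 ± 0.74 and from 15.2 ± 1.94 to 1.10 ± 0.74 (0.00033 and 0.004), and a 27 kDa glycoprotein (BGIBMGA000462) from 194 ± 139 to 13.1 ± 0.58 and from 115 ± 7.55 to 20.2 ± 10.9 (0.0007 and 0.011). In WT, uricase (BGIBMGA001333), which breaks down uric acid, fell from 8.65 ± 1.31 to 0.62 ± 0.34 (0.002), and HSP20.4, a small heat shock protein, rose from 2869 ± 1543 to 7237 ± 1421 (0.035). The call of HSP20.4 ended in 8 of 17 alternatives, among them without WT P2 replicate 1 or 3 or any WT P4 replicate (adjusted p up to 0.15), and that of the glycoprotein in TBH in 4 of 17, among them quantile normalization and without TBH P2 replicate 1 or 2 or TBH P4 replicate 1 (up to 0.10).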
